A study of Mus musculus with 2 samples.

How the data were processed

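Single-cell RNA sequencing libraries from islets of C57BL/6 mice were compared, 1 from wild type mice and 1 from mice overexpressing miR-503 in beta cells. Per the labels' protocols islets were dissociated for 5 min at 37 °C in 0.08% trypsin and 0.006% EDTA, and cells were captured with 10x Chromium 3 prime reagents, version 2. Per the submitters' processing notes reads were handled with Cell Ranger 2.1.0, STAR 2.5.1b and the mouse build mm10. The annotation release, the sequencing batches and the filter behind the deposited barcodes were not given in the sources used here. The deposited values are counts, the whole numbers of UMIs per gene and cell, with no normalization. Over all deposited barcodes total UMIs per cell ran from 5727 to 88243 in the wild type and from 6671 to 94943 in the transgenic library.

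Cells were kept with at least 500 detected genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrially encoded genes, which removed 20 wild type and 15 transgenic barcodes. Doublets were scored per library with Scrublet in scanpy 1.11.5 at an expected rate of 4%. Its automatic threshold marked 2 (0.0442%) and 6 (0.145%) cells, under the fixed limit of 0.5%, so the top 4% of scores were removed, 181 and 166 cells. The kept cells had a median of 3393 and 3286 detected genes and 2.99% and 2.08% mitochondrial UMIs. Both libraries were clustered together without integration: log-normalised values, 2000 variable genes, 30 principal components, exact search for 15 neighbours, edges weighted by shared neighbours, and Leiden clustering in igraph 0.11.9 at resolution 1.0 with 20 iterations and a fixed seed. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

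The 24 clusters were named from fixed marker genes. A marker counted if some cluster reached 20 CPM, and a class score was the mean over markers of a cluster's CPM as a share of the highest cluster. A name needed a score of at least 0.3, at least 3 markers at 25% of the highest cluster, and no other class at 75% of the best score. A cluster also stayed unnamed if its 10 leading genes held more markers of another class, if Ptprc reached 20 CPM outside immune classes, if Ins2 reached 100000 CPM outside beta-like cells, or if the hormone of another endocrine class passed 5 times the class median and 1000 CPM. These rules named 16 clusters and left 8 unnamed. The cell filter, markers, gene lists, resolution, numbers of components and neighbours and rules for naming genes were fixed before the data were examined. The neighbour graph, the single level of clustering and the thresholds for naming clusters were not: an approximate neighbour graph, which put acinar with beta cells and varied between runs, a second level of clustering and looser naming rules were tried and set aside after their clusters had been seen. Clustering each cluster again was kept as an alternative.

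UMIs were summed over the cells of a class in each library and scaled by TMM factors. Ratios carry exact conditional binomial 95% intervals and shares exact Clopper-Pearson 95% intervals. Where a count is 0, the limit is 3 counts. Differences between classes carry a delta-method counting interval. Classes with at least 50 cells in both libraries were compared: beta-like, alpha-like, delta-like and gamma-like. The sum of a class is 1 value per group, so no test across samples was made. Genes were named in beta-like cells as the 12 highest and 12 lowest ratios among those with at least 100 UMIs over both libraries and 20 CPM in at least 1, leaving out markers of other types, sex-linked genes and genes over 5 times more abundant in another class. Also named were up to 4 members per list with at least 100 UMIs and the largest ratios in either direction, the 4 highest and 4 lowest genes in other classes, the 6 highest and 6 lowest beta minus alpha differences, and by prior interest Insr, Jazf1, Cdkn1a, Cdkn2a, Cdkn2b, Trp53, Ins1, Ins2, Mafa, Ucn3, Ccnd1, Ccnd2, Ccne1 and the miR-503 host transcript. Genes outside these rules (Gm28730, Hamp in beta-like cells, Snhg11 in beta-like cells, Erdr1 and PISD across classes, and those shared by beta-like and alpha-like cells) were chosen after their values were seen. Of the genes selected by these rules or by opposite ratios in beta-like and alpha-like cells, 3 are not reported here, and they stay in all counts and list medians.

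For each of 24 gene lists, the median log2 ratio of members with at least 50 UMIs was placed among 10000 random lists of the same size drawn from 20 bins of expression. The lists are beta identity, granule and exocytosis, exosome and multivesicular body, senescence and secretome, p53 and DNA damage, cell cycle, miR-503 family targets, insulin signalling, unfolded protein response, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, glycolysis and disallowed, dedifferentiation, immediate early and dissociation stress, interferon, MHC class I, ribosomal proteins, cholesterol and lipid, oxidative stress, sex-linked, miR-503 host and neighbours, macrophage activation, alpha function and endothelial. Symbols absent from the gene table were Alix, Vps28, Mx2 and 8 of the host list. Seed sites were sought in the longest 3 prime UTR of at least 8 bases per gene in GENCODE M21 on GRCm38, with random lists matched also on 10 bins of UTR length. Shares of cells with a UMI were taken in cells thinned to 3000 UMIs, insulin UMIs included. Insulin shares were compared in 10 bins of depth, and shifts of site genes were bootstrapped 2000 times over genes.

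The procedure was tested on simulated data made from the beta-like and alpha-like sums with known ratios. Counts were Poisson draws from the pooled profile of each class, and genes in the lists and site sets varied independently. No free RNA, cell states, library differences or matching on UTR length were simulated. The rates below are therefore not error rates for these libraries. In beta-like cells (11848 genes, 200 changed) intervals covered the true ratio for 95.3% of genes and excluded no difference for 100% of 100 genes at 2-fold and 96 genes at 4-fold, while 1 of 11652 unchanged genes reached 2-fold. In alpha-like cells (7873 genes) coverage was 95.2% and recovery 100% of 90 genes at each size. Of 200 random lists 3% and 5% fell outside the 95% range and all shifted lists were found. The shift given to these lists was larger than most list medians below, so recovery of smaller list shifts was not tested. Of 50 sets of 700 site genes shifted by −0.05, 96% and 98% fell below the 2.5 percentile, against 6% and 2% of unshifted sets. TMM factors differed from those of edgeR 4.0.16 by at most 4.56e-09.

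Alternatives covered scaling (total UMIs, total UMIs without hormone and mitochondrial genes, per-cell means), cell filters, doublet removal, resolution, each library clustered alone, variable genes without hormones, gene minimums, a 1.5-fold threshold, thinning depth and other seed sites. Those added after the data were seen are clusters split again, cells with Y-linked UMIs and no Xist, cluster 9 alone, without cluster 22, and the description of macrophage-like and B cell-like cells. Expression in unnamed clusters and in T cell-like cells was not compared because of mixed markers or few cells.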

Results

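Single-cell RNA sequencing was carried out on pancreatic islets from C57BL/6 mice at postnatal day 70 (10 weeks), the islets being small endocrine organs made of insulin-producing beta cells, glucagon-producing alpha cells, somatostatin-producing delta cells and gamma cells that make pancreatic polypeptide. There were 2 libraries, 1 from wild type mice and 1 from mice that overexpress the microRNA miR-503 in beta cells, each prepared by droplet capture that counts the 3 prime ends of transcripts by unique molecular identifiers (UMIs). The deposited wild type matrix held 4540 barcodes with 104677537 UMIs, and the transgenic matrix held 4158 barcodes with 109243270 UMIs. After filtering and doublet removal 4339 wild type and 3977 transgenic cells remained, with a median of 21496 and 24583 UMIs per cell. The number of mice behind each library was not given in the sources used here. With 1 library per group no difference below has a replicate check, no test was possible, and the 95% intervals (exact conditional binomial for ratios of UMIs, exact Clopper-Pearson for shares) cover counting error only. Ratios are given as log2 of the transgenic over the wild type library.

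The targeted gene itself could not be read from these libraries. Mir503 lies on chromosome X at 53053984 to 53054054 of GRCm38, on the minus strand within a cluster of microRNA genes, and a mature microRNA carries no poly(A) tail for 3 prime capture. Of the 9 fixed symbols for the host transcript and its neighbours only Plac1, a gene of the placenta, was in the gene table, and it had 0 UMIs in both libraries. The noncoding gene Gm28730, picked afterwards by its position on the same strand at 53051194 to 53053159, had 0 UMIs in wild type and 1 UMI in transgenic cells. In beta-like cells it had 0 UMIs in each library, where 0 counts allow up to 0.0374 and 0.0368 counts scaled to library size (CPM), so the counts neither bear out nor contradict the genotype labels.

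The libraries differed in sex makeup. Xist, the RNA that silences an X chromosome in female cells, had 12 UMIs in the wild type and 6415 UMIs in the transgenic library. A Y-linked UMI without Xist was found in 81.3% of wild type (80.1 to 82.5) and 68.4% of transgenic cells (66.9 to 69.9), and Xist without a Y-linked UMI in 2 wild type and 310 transgenic cells. Both were found in 10 wild type and 231 transgenic cells, so these UMIs do not part the sexes cleanly. In beta-like cells the fixed list of 6 sex-linked genes had 3 members higher and 3 lower, with a median of −0.05 at percentile 41.5 that turned to 0.02 in cells with at most 5% mitochondrial UMIs. Xist stood at 8.80, and the Y-linked genes Ddx3y, Eif2s3y and Uty, which are expressed in male cells, at −0.32, −0.30 and −0.19.

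The makeup of the islet cell suspensions was compared because the transgene acts in beta cells. Beta-like cells made up 73.9% of wild type cells (72.6 to 75.2) and 64.8% of transgenic cells (63.3 to 66.3). Alpha-like cells made up 10.0% (9.15 to 10.96) and 16.7% (15.5 to 17.9), and delta-like cells 2.88% (2.40 to 3.42) and 5.76% (5.05 to 6.53). Among the 3825 wild type and 3538 transgenic cells given an endocrine name, the beta-like share was 83.8% against 72.8%, the alpha-like share 11.4% against 18.7% and the delta-like share 3.27% against 6.47%. Gamma-like cells were at 1.54% (1.18 to 1.99) and 1.95% (1.52 to 2.46), whose intervals overlap. Macrophage-like cells numbered 65 and 42, B cell-like cells 21 and 54, and T cell-like cells 1 and 13. The naming thresholds were set after the clusters had been seen, and 9.84% of wild type and 8.30% of transgenic cells stayed unnamed. The suspension was made with trypsin and median depth differed between classes, both of which can set such shares.

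**Figure D1:**
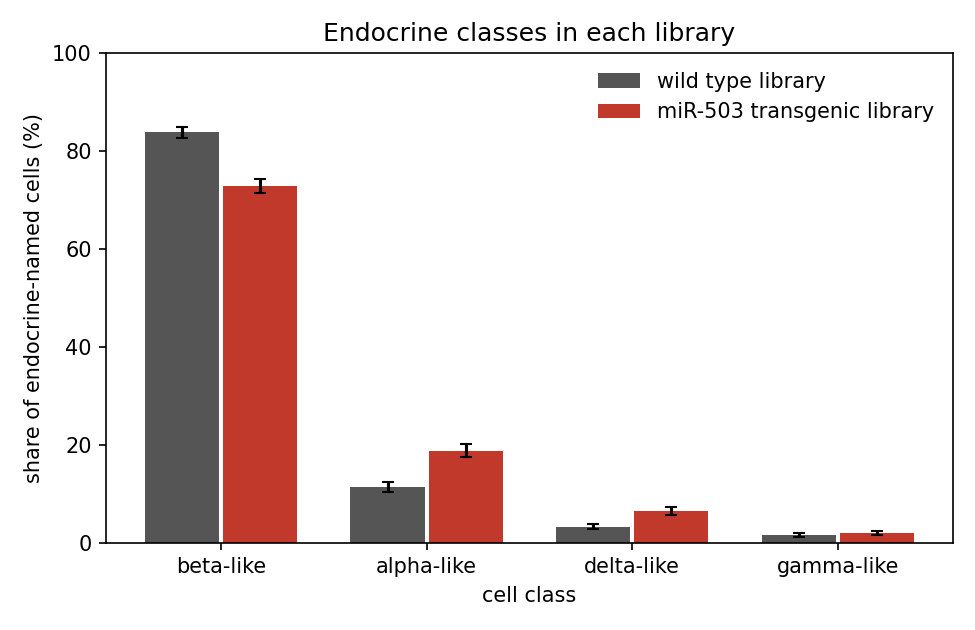
Share of endocrine-named cells in each class (vertical axis, percent; horizontal axis, cell class) for the wild type and transgenic libraries, with exact 95% binomial intervals that cover counting error only. Beta-like cells stand at 83.8% in the wild type and 72.8% in the transgenic library, alpha-like cells at 11.4% and 18.7%.

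The main question was how beta cells with extra miR-503 differ in their transcripts, which the series title ties to insulin granules, insulin resistance and beta-cell senescence. The insulin genes took a larger part of the transcripts in transgenic beta-like cells. Ins1 (ENSMUSG00000035804, chromosome 19, 52264297 to 52265476) was 1.59-fold higher at log2 0.67 (0.66 to 0.67), and Ins2 (ENSMUSG00000000215, chromosome 7, 142678656 to 142743381) was 1.47-fold higher at 0.55. Together they made up 50.6% of wild type and 60.4% of transgenic beta-like UMIs, a difference of 9.75 percentage points, against 2.77% and 2.90% in alpha-like cells. Beta-like cells were also deeper, with medians of 22988 and 28997 UMIs. The median cell held 11103.5 and 17204 insulin UMIs, and 11666.5 and 11594 other UMIs. When cells were sorted into 10 bins of equal depth, the insulin share was higher in transgenic cells in 10 of 10 bins, by 4.70 to 9.50 points. Different clusters held most of the class in each library: clusters 0, 1 and 2 held 85.1% of wild type and 21.6% of transgenic beta-like cells, and clusters 4, 5 and 6 held 10.4% and 71.7%. Ins1 and Ins2 were among the leading genes of clusters 4, 5 and 6, and stress-responsive genes (Fos, Egr1, Arc, Jun and Npas4 in cluster 1, Fos, Jun and Egr1 in cluster 5, Fosb in cluster 4) led some of them.

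**Figure D2:**
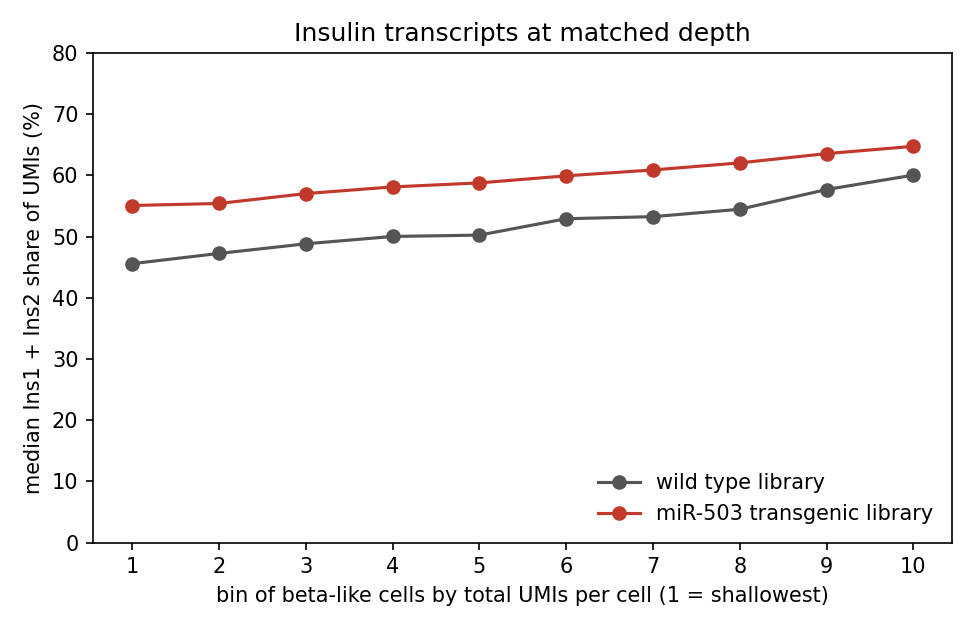
Median share of UMIs from Ins1 and Ins2 (vertical axis, percent) in beta-like cells of each library, in 10 bins of cells of increasing total UMIs (horizontal axis). The transgenic median lies above the wild type median in all 10 bins, from 55.1% against 45.6% in the shallowest to 64.8% against 60.1% in the deepest.

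Outside insulin, few abundant genes differed by 2-fold. Among the genes fixed for naming, Pdyn, the precursor of the dynorphin opioid peptides, stood highest, 4.29-fold higher (3.87 to 4.77; chromosome 2, 129686565 to 129699844). An unnamed cluster that scored highest for beta, with 31 wild type cells and 1 transgenic cell, also had Pdyn among its leading genes. That cluster was left out of the beta-like sums behind this ratio. Th, the rate-limiting enzyme of catecholamine synthesis, was 2.98-fold higher at 1.57 (1.49 to 1.66) and Dapl1 2.65-fold higher. Dsp, the desmosome protein desmoplakin (chromosome 13, 38151294 to 38198577), stood lowest at −1.62 (−1.76 to −1.47), 3.07-fold lower. It was followed by Cldn7, a claudin of tight junctions, at −1.02, Eps8l2, an actin regulator, at −0.999, and the metal-binding protein metallothionein Mt2 at −0.98. The other genes named at the high end were 6330403K07Rik at 1.79, Gm30173, Krtap17-1, Dhrs7, Copz2 of the vesicle coat, the purinergic receptor P2ry1, Exoc7 of the exocyst and the transcriptional cofactor Lmo1, the last 7 between 0.75 and 0.87. At the low end were Pi4k2a, Fkbp1b, Gstm1, Ubl5, Erdr1, Fgd2, the cyclic nucleotide phosphodiesterase Pde10a and PISD, all between −0.89 and −0.80. Erdr1 was lower in every endocrine class, at −0.90 in alpha-like, −0.57 in delta-like and −0.95 in gamma-like cells, and PISD was at −0.76 in alpha-like cells.

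Of 3421 genes with at least 100 UMIs and 20 CPM, 15 were at least 2-fold higher, 3 at least 2-fold lower and 97.3% within 1.5-fold. Of these, 5 higher and 2 lower genes were neither markers of another cell type, sex-linked nor over 5 times more abundant in another class. With no CPM minimum 191 of 11864 genes were at least 2-fold higher and 107 lower. Of these, 124 and 60 were over 5 times more abundant in another class. With markers of other types and sex-linked genes also left out, 49 and 41 of 7489 genes remained. Because insulin fills so much of each profile, scaling by total UMIs in place of trimmed means (TMM) moved the median of all genes by −0.33 and gave 125 higher and 298 lower, so ratios below are relative to the bulk of genes.

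**Figure D3:**
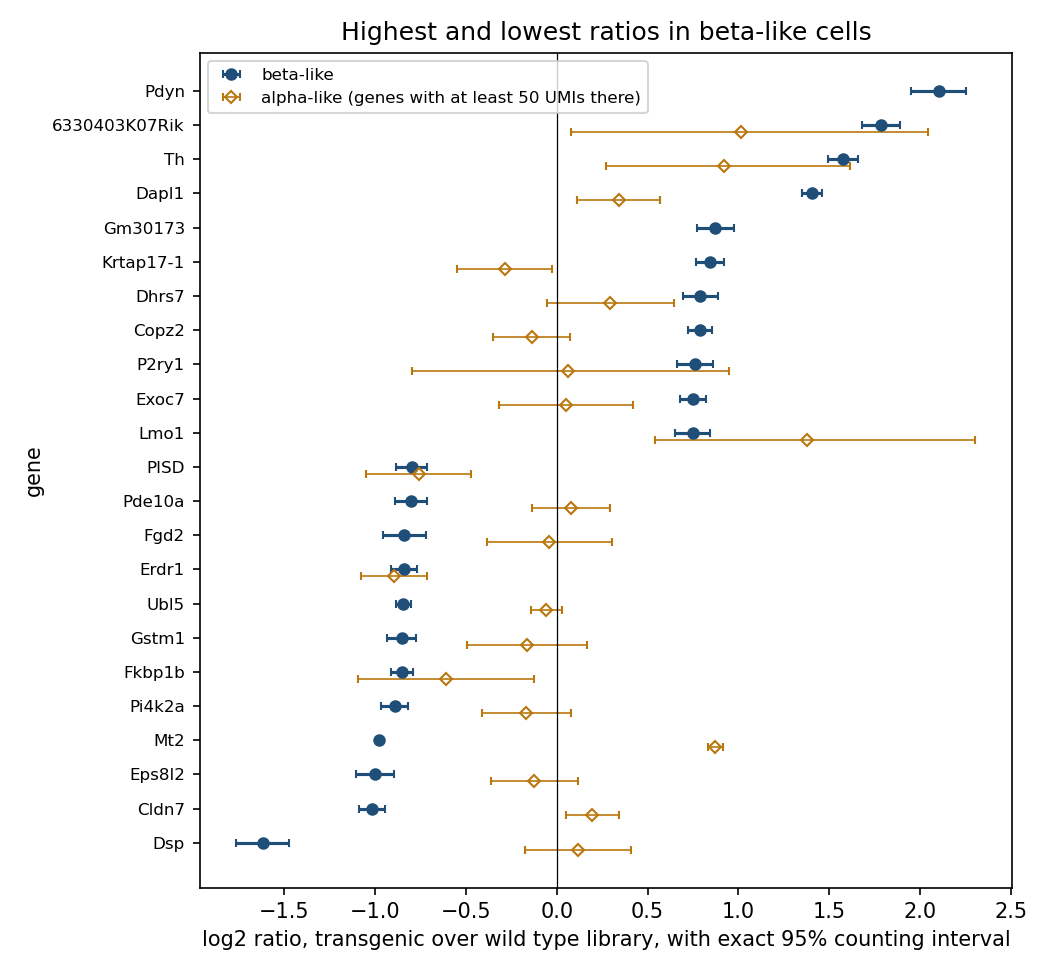
Log2 ratio of the transgenic over the wild type library (horizontal axis) for 11 of the highest and the 12 lowest named genes (vertical axis) in beta-like cells, filled circles, and in alpha-like cells, open diamonds, with exact 95% counting intervals. In beta-like cells Pdyn stands 4.29-fold higher and Dsp at −1.62, and in alpha-like cells Dsp is at 0.12.

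Gene lists fixed before the data were examined were described by their median ratio and its percentile among 10000 random lists of the same size matched on expression. Free RNA of other cells can add to genes over 5 times more abundant in another class, which include every named member of the interferon and cell cycle lists, Cd9, Cd82, Smpd3, H2-Q6, H2-Q4, Tapbp, Cdkn1a, Cdkn2a, Trp53, Insr, Ccne1, E2f3, Fgfr1, Grb10, Igfbp3, Timp2, Ldha, Slc2a1, Gast, Cck, Serpina7, Scd1, Gpx3, Hmox1, Ccl2, Cxcl1, Plk2, Phlda3, Gadd45b, Atf3, Hspb1, Ndufa1, Abcc8, Pik3cb, Rpl15, Rps9, Rps3 and Rpl27. Respiratory chain genes split by genome. Of the 61 nuclear-encoded subunits of oxidative phosphorylation 53 were higher and 8 lower in transgenic beta-like cells, with a median of 0.18 at percentile 100 that turned to −0.15 under total scaling and to −0.04 in cluster 9 alone. Ndufa1 (0.59), the ATP synthase subunit Atp5o (0.43) and Uqcrc2 (0.39) were among those farthest from 0. All 13 subunits encoded by the mitochondrial genome were lower, with a median of −0.28 at percentile 0.02, led by mt-Nd4l (−0.61), mt-Nd5 (−0.39), mt-Co2 (−0.35) and mt-Nd1 (−0.30). The median mitochondrial share of UMIs was 3.26% in wild type and 2.02% in transgenic beta-like cells, a measure that also follows cell quality. The mitochondrially encoded list was at −0.10 in alpha-like cells (11 of 12 lower), −0.11 in delta-like and −0.14 in gamma-like cells (12 of 12 lower in each).

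Sterol synthesis and interferon-induced genes were lower in transgenic beta-like cells. In the cholesterol and lipid list 16 of 20 members were lower, with a median of −0.35 at percentile 0 (−0.14 in cluster 9 alone). Hmgcs1, which makes the precursor of mevalonate, was at −0.66 (−0.71 to −0.62), Cyp51 at −0.59 and Idi1 at −0.58, while the desaturase Scd1 was at 1.48 on 31 and 70 UMIs. In the interferon list 18 of 22 were lower, with a median of −0.34 at percentile 0, led by Ifit1 (−1.31), Oasl2 (−1.16) and Rsad2 (−0.97), antiviral proteins, with Ifi27l2a at 2.65. In macrophage-like cells, where these genes are more abundant, 19 of 22 were lower with a median of −0.98. In the MHC class I list 11 of 13 were lower, with a median of −0.15 at percentile 3.63, inside the range of random lists (−0.16 to 0.14). H2-Q6 stood at −0.76, H2-Q4 at −0.54, Tapbp at −0.29 (0.07 in cluster 9 alone) and H2-K1 at −0.28. Of 20 oxidative stress genes 14 were lower, with a median of −0.15 at percentile 0.36. Mt2, Mt1 (−0.75) and the heme-degrading Hmox1 (−0.67) were lower, and the secreted peroxidase Gpx3, which is more than 5 times as abundant in another class, was at 1.09. Of 19 glycolysis and disallowed genes, those kept low in mature beta cells, 13 were lower with a median of −0.13 at percentile 3.58, also inside its range. The glucose transporter Slc2a1 was at −0.81 and Eno2 at −0.36, while the lactate dehydrogenases Ldha, at 1.52 in alpha-like cells too, and Ldhb were at 1.68 and 0.70.

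Beta-cell identity and secretory genes had medians inside the range of random lists. Of 24 identity genes 15 were higher with a median of 0.07 at percentile 78.7, which turned to −0.26 under total scaling. Beside Ins1 and Ins2, the glucose transporter Slc2a2 stood at −0.37 and the potassium channel subunit Abcc8 at 0.29 (−0.04 under total scaling). The peptide Ucn3, a marker of maturity, was at −0.14 (−0.17 to −0.11). The maturity factor Mafa had only 9 and 11 UMIs over 3206 wild type and 2577 transgenic cells, at 0.60 (−0.81 to 2.05). No difference was detectable on so few UMIs, and why so few were counted was not tested. Of 28 granule and exocytosis genes 17 were higher, with a median of 0.08 at percentile 90.5 (−0.25 under total scaling). Doc2b, a calcium sensor of exocytosis, was at 1.13, the granule GTPase Rab3a at 0.52, the granin Scg2 at 0.48 and the priming factor Unc13a at −0.45. Of 25 exosome and multivesicular body genes 16 were lower, with a median of −0.11 at percentile 3.86. The tetraspanins Cd9 and Cd82 stood at −1.19 (−1.37 to −1.01) and −0.42, the budding protein Pdcd6ip at −0.38 and the sphingomyelinase Smpd3 at −0.34. The unfolded protein response list had 14 of 25 higher and a median of 0.02 at percentile 37.3 (−0.31 under total scaling), with Manf at 0.37, Sdf2l1 at 0.32 (−0.01 under total scaling), Atf3 at −0.53 and Syvn1 at −0.26. Of 75 cytosolic ribosomal protein genes 64 were higher, with a median of 0.09 at percentile 89.8 that turned to −0.24 under total scaling. Rpl15 (0.23), Rps9 (0.22), Rps3 (0.21) and Rpl27 (0.21) turned negative with it.

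**Figure D4:**
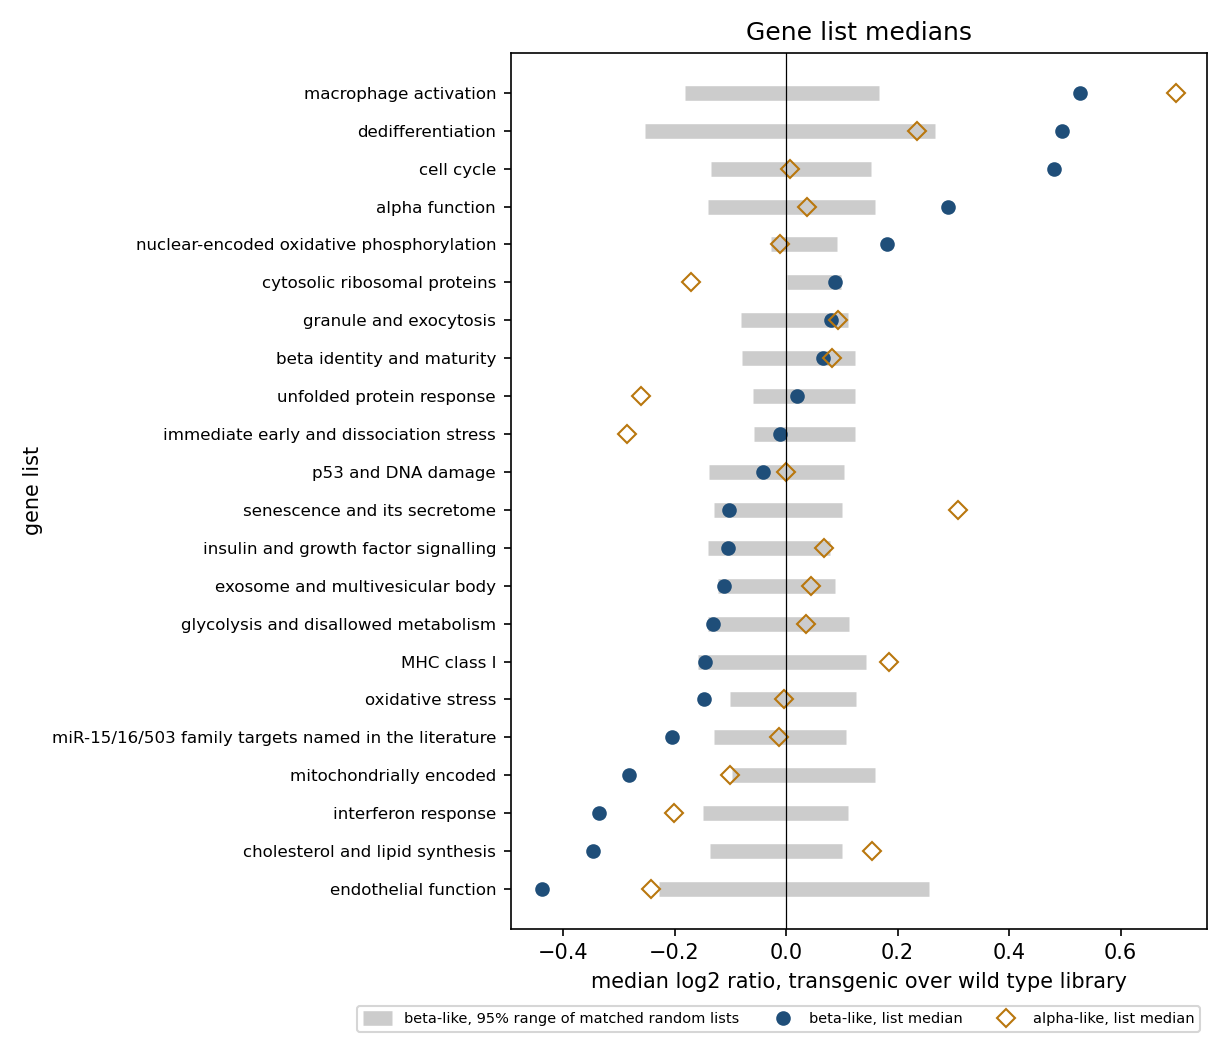
Median log2 ratio of the transgenic over the wild type library (horizontal axis) for each fixed gene list (vertical axis) in beta-like cells, filled circles, and alpha-like cells, open diamonds, with the 95% range of matched random lists in beta-like cells as grey bars. The cholesterol list is at −0.35 and the oxidative phosphorylation list at 0.18 in beta-like cells (−0.15 under total scaling).

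Senescence genes, the subject of the series title, did not stand higher as a list. Of 33 members 15 were higher and 18 lower, with a median of −0.10 at percentile 7.18. In summed UMIs, which do not set free RNA apart, the cyclin-dependent kinase inhibitors that mark senescent cells stood below 0: Cdkn1a (p21) at −0.30 (−0.35 to −0.25), Cdkn2a, whose 3 prime counts do not part p16 from p19, at −0.50 (−0.90 to −0.10) on 145 and 83 UMIs, and Cdkn2b at −0.30 (−0.43 to −0.18). Trp53, the tumour suppressor that induces Cdkn1a, was at 0.29 (0.18 to 0.40), which turned to −0.04 under total scaling and −0.17 in cluster 9 alone. The 4 members farthest from 0 were Ccl2 (2.08), Timp2 (1.05), Igfbp3 (−0.99) and Cxcl1 (0.78), of which the chemokines Ccl2 and Cxcl1 were at 4.06 and 2.09 in alpha-like cells. Of 22 p53 and DNA damage genes 12 were lower, with a median of −0.04 at percentile 36.1 that was 0.00 with per-cell means. Its members Plk2 (−0.79), Phlda3 (0.77), Gadd45b (0.58) and the repair factor Xpc (−0.54) went both ways. In cells thinned to 3000 UMIs, which left out no cell, Cdkn1a was detected in 21.5% of wild type (20.1 to 22.99) and 15.3% of transgenic beta-like cells (14.0 to 16.8), and unthinned in 73.3% and 65.3%. The 3000 UMIs include insulin, which took 50.6% of wild type and 60.4% of transgenic beta-like UMIs. Thinned transgenic cells therefore kept fewer other UMIs, which lowers the thinned shares of other genes there. Before thinning the median beta-like cell held 11666.5 and 11594 UMIs outside insulin. Macrophage-like cells, with median depths of 10713 and 10248.5 UMIs, had Cdkn1a in 84.6% and 61.9% after thinning and 95.4% and 88.1% before. These shares were above those of beta-like cells, so macrophage-like cells set no background level for Cdkn1a. How much of the beta-like share is free RNA was not tested. Cdkn2a was detected in 0.374% and 0.349% of thinned beta-like cells and 4.21% and 3.03% unthinned. It was found in 0 of 65 and 0 of 42 thinned macrophage-like cells, which allows up to 4.62% and 7.14%, and in 3.08% and 0% unthinned, so it cannot be set apart from background.

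Cell cycle genes were higher in transgenic beta-like cells, and many of the miR-503 family's known targets were lower. Of 30 cell cycle genes 24 were higher, with a median of 0.48 at percentile 100. Top2a, the topoisomerase of dividing cells, was at 3.05 (2.47 to 3.68) on 28 and 187 UMIs, Cdc20 at 2.68, Cdk1 at 2.26 and Ccnb1 at 2.07. A cluster of dividing cells, cluster 22, held 5 wild type and 26 transgenic beta-like cells and gave 46.4% and 73.3% of the Top2a UMIs. Without it the list median was 0.26, and in cluster 9 alone it was −0.14. Top2a was detected in 0.0936% of wild type and 0.504% of transgenic beta-like cells thinned to 3000 UMIs, and in 0.499% and 2.33% unthinned. Among macrophage-like cells it was found in 1.54% and 0% (up to 7.14%) both ways. Of 28 targets of the miR-15, miR-16 and miR-503 family named in the literature 20 were lower and 8 higher, with a median of −0.21 at percentile 0.07 (−0.07 in cluster 9 alone). The G1 cyclin Ccne1 was at −0.95 (−1.58 to −0.35) on 79 and 33 UMIs, the cell cycle factor E2f3 at −0.81, the growth factor receptor Fgfr1 at −0.65 and the neurotrophin Bdnf at 0.78. The D-type cyclins Ccnd1 and Ccnd2 stood at −0.33 (−0.40 to −0.26) and 0.05 (0.03 to 0.07), the latter −0.28 under total scaling. Of 25 insulin and growth factor signalling genes 21 were lower, with a median of −0.10 at percentile 10.0 (0.00 in cluster 9 alone). The adaptor Grb10, which restrains insulin signalling, was at −0.92, Igf1r at −0.49 and Pik3cb at 0.35. The insulin receptor Insr was at −0.25 (−0.42 to −0.09), against 0.09 in cluster 9 alone, and Jazf1 at −0.09 (−0.36 to 0.17), against 0.02 in cells with Y-linked UMIs and no Xist.

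Sites for the miR-503 seed gave a measure that does not depend on chosen targets but is not particular to miR-503. A microRNA lowers transcripts that pair with its seed, the bases near its 5 prime end, and the 7-base site for miR-503, CGCTGCT, was present in the longest annotated 3 prime UTR of 720 of 12033 searched genes. Their median ratio in beta-like cells was −0.089, against −0.011 for genes with no site, a shift of −0.078 that ranked 5 of 210 among sites of the same base composition. The median lay at percentile 0.02 of 10000 random lists matched on expression and UTR length, whose own median was −0.055. The site ending in A opposite the first base, GCTGCTA (1396 genes), gave a shift of −0.074 at percentile 0.03, and the miR-15/16 site TGCTGCT (3329 genes) −0.084 at percentile 0. Both share the bases GCTGCT with the 7-base miR-503 site, so the values do not part miR-503 from miR-15/16. The 8-base site CGCTGCTA (73 genes) gave −0.093 at percentile 9.02. In alpha-like cells the shift for CGCTGCT was −0.022 over 576 of 9583 genes, at percentile 1.61 and rank 6 of 210. There the 8-base site was at percentile 1.70, GCTGCTA at 10.9 and TGCTGCT at 10.05. Within cluster 9 alone, which holds 142 wild type and 148 transgenic cells, the shift was −0.024.

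Markers of other cell types differed within beta-like cells as well, where free RNA or mixed droplets were not set apart from expression. Of 59 such markers with at least 100 UMIs 17 were at least 2-fold higher and 6 at least 2-fold lower. In the macrophage activation list 9 of 14 were higher, with a median of 0.53 at percentile 100, where Ccl2 and the lysozyme Lyz2 (1.68) were higher and the chemokines Ccl4 (−1.09) and Ccl3 (−1.07) lower. In macrophage-like cells the same list was at −0.34 with 11 of 15 lower and 4 higher, among them Lyz2 at 1.96 and Ccl2 at 1.56. Of 17 alpha function genes 12 were higher, with a median of 0.29 at percentile 99.98 that turned to −0.04 under total scaling. Among them were Irx1 (0.95), Gcg (0.76), Ttr (0.73) and Irx2 (0.64). Of 14 endothelial genes 11 were lower, with a median of −0.44 at percentile 0.04 (−0.14 in cluster 9 alone), led by Flt1 (−1.67), Esm1 (−1.55), Plvap (−1.17) and Kdr (−1.02). An unnamed cluster with endothelial and red cell transcripts held 109 wild type and 27 transgenic cells. Of 10 dedifferentiation genes 7 were higher, with a median of 0.49 at percentile 99.97. Their largest ratios were those of the gut hormones Gast (−2.81) and Cck (−1.79), Ldha and Serpina7 (1.53). An unnamed cluster led by Gast, Cck and Pdyn held 31 wild type cells and 1 transgenic cell. In the immediate early and dissociation stress list 11 of 25 were higher, with a median of −0.01 at percentile 18.2, which was 0.04 with per-cell means and 0.00 without cluster 22. The heat shock genes Hspb1 (0.67) and Hspa1a (0.55) were higher and Atf3 and Nr4a1 (−0.50) lower.

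Alpha-like cells were compared to see which differences the libraries share, since the labels describe the transgene as specific to beta cells. Their largest cluster held 292 of 435 wild type and 605 of 663 transgenic cells, and the next held 102 and 29. Dissociation stress, unfolded protein response and ribosomal genes were lower in transgenic alpha-like cells, and genes of the senescence and secretome list were higher. The inducible chaperones Hspa1b and Hspa1a were 3.25-fold lower at −1.70 (−1.77 to −1.63) and 2.63-fold lower at −1.40 (−1.45 to −1.34). The immediate early and dissociation stress list had 20 of 25 members lower (median −0.29, percentile 0), the unfolded protein response list 23 of 25 (−0.26, percentile 0) and the ribosomal list 75 of 75 (−0.17, percentile 0). The senescence and secretome list had 18 of 25 members higher (0.31, percentile 100), the MHC class I list 9 of 13 (0.19, percentile 99.1), the cholesterol list 14 of 19 (0.15, percentile 98.9) and the granule list 18 of 26 (0.09, percentile 98.2). Shared in direction with beta-like cells were the interferon list, with 13 of 19 lower (−0.20, percentile 0.275), the endothelial list, 7 of 8 lower (−0.24, percentile 1.67), and the macrophage activation list, 6 of 11 higher (0.70, percentile 100). Leaving out markers of other types, sex-linked genes and genes over 5 times more abundant in another class, highest were Hamp, which encodes the iron hormone hepcidin, at 2.09 (1.61 to 2.60) and at 1.96 in beta-like cells, Tmem158 at 1.45, the transcription factor Sox4 at 1.17 and Zfp697 at 1.04. Swt1 (−1.20) and Lman2l (−1.02) were lowest after the chaperones within the same limits. The miR-503 target list had a median of −0.01 at percentile 44.5 and the cell cycle list, with only 15 of 30 members measured, 0.01 at percentile 55.1. Among its members Stmn1 was at 1.95 (1.32 to 2.64) in alpha-like cells. Of 4502 genes 19 were at least 2-fold higher and 8 lower.

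In delta-like cells 10 of 4219 genes were at least 2-fold higher and 5 lower. With the same genes left out, the import receptor Ipo5 was highest at 1.27 (0.61 to 1.99), followed by Krtap17-1 (1.14), Coprs (1.13) and the lysosomal sulfatase Arsb (1.07). The noncoding RNA Snhg11 was lowest at −1.80 (−2.29 to −1.33) and stood at −1.60 in beta-like cells, followed by A330069E16Rik (−1.08), Galnt18 (−1.05) and the homeobox factor Pbx3 (−1.03). In gamma-like cells, with 59 and 69 cells, 4 of 1887 genes were at least 2-fold higher and 6 lower. The dynactin subunit Actr1b was at 1.03 (0.45 to 1.63), the G-protein regulator Rgs4 at 0.94, Prr7 at 0.81 and Ndfip2 at 0.76. Tmem108 was lowest at −2.37 (−3.02 to −1.76), followed by the tubulins Tuba4a (−0.96) and Tubb4b (−0.81) with Erdr1 between them. Ribosomal protein genes were lower in both classes, 65 of 75 in delta-like (median −0.07, percentile 0.765) and 70 of 75 in gamma-like cells (−0.09, percentile 0.02). In gamma-like cells the cholesterol list had 8 of 9 members lower (−0.51, percentile 0.07) and the senescence and secretome list 8 of 11 higher (0.25, percentile 98.1). In delta-like cells 19 of 25 immediate early and dissociation stress genes were lower (−0.16, percentile 0.01). The beta identity list had 12 of 18 members higher there (0.15, percentile 99.2). The macrophage activation list was split, with 7 of 20 members measured, 4 higher and 3 lower (0.41, percentile 99.75).

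Setting beta-like against alpha-like ratios removes what both classes of a library share in equal size, but not a shared difference of unequal size such as that of Ccl2. The ratios, not the levels, of the collagen chaperone Serpinh1 and the heat shock genes Hspa1a and Hspa1b were higher in beta-like than in alpha-like cells. Those of the metallothionein Mt2 and the desmosome gene Dsp were lower. For Hspa1a and Hspa1b most of the difference came from alpha-like cells, at −1.40 and −1.70 against 0.55 and 0.27 in beta-like cells. Over 8143 genes with at least 100 UMIs in each class the difference was highest for Serpinh1 at 2.46 (2.18 to 2.74), Kdelr3, a retrieval receptor of the endoplasmic reticulum, at 2.28, Caly at 2.03, Hspa1b at 1.97, the transcription factor Foxp2 at 1.97 and Hspa1a at 1.95. It was lowest for Ccl2 at −1.98, Gm12216 at −1.96, Mt2 at −1.85 (−1.89 to −1.81), Myh14 at −1.84, Dnase2a at −1.76 and Dsp at −1.73. The classes' ratios had a Pearson correlation of 0.318 across genes, which are not independent replicates. In both classes 22 genes were at least 2-fold higher and 2 at least 2-fold lower. Among the former were the pancreatic enzymes Prss2 (3.74 in beta-like, 3.24 in alpha-like), Ctrb1 (2.78 and 2.38) and Cela2a (2.98 and 2.31), the lymphoid chemokine Ccl21a (5.45 and 5.33), Lyz2 and Xist, and the latter were Gast and Ccl4.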

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

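Tests chosen after the result was seen were those on free RNA from dividing immune cells, UTR length and expression, a difference shared by all cells and free insulin RNA, and the settings limited to cells with Y-linked UMIs and no Xist, to cluster 9 or without cluster 22. Sex was told only by Xist and Y-linked UMIs, and 231 transgenic cells held both. The tests on female cells hold only as far as these UMIs part the sexes. Beta-like and alpha-like cells of the same libraries went opposite ways for 4 of 3187 genes at 1.5-fold or more in each class, of which 3 are given here, and 1 gene list lay outside its random range on opposite sides in the 2 classes. These differences between the classes were not tested. The collagen chaperone Serpinh1 was higher in transgenic beta-like cells at 1.07 (0.96 to 1.18) and lower in alpha-like cells at −1.38 (−1.65 to −1.12), a difference of 2.46. The metallothioneins were lower in beta-like and higher in alpha-like cells, Mt1 at −0.75 and 0.63, a difference of −1.39, and Mt2 at −0.98 and 0.87, a difference of −1.85. The cholesterol and lipid list had a median of −0.35 in beta-like and 0.15 in alpha-like cells, a difference of −0.50. In cluster 9 alone the beta-like value was −0.14. Gamma-like cells, with 9 of 20 members measured, stood at −0.51 with 8 lower, 2 of them with an interval below 0. Delta-like cells stood at 0.14 with 8 of 14 members higher. The list was thus lower in gamma-like cells too, on few members, but not in delta-like cells.

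Cell cycle genes were higher in transgenic beta-like cells. The values argue against cluster 22 alone and against female cells as the whole cause. Without cluster 22 the median of 27 members was 0.256, above the range of matched random lists (−0.150 to 0.162). Cells with Y-linked UMIs and no Xist gave 0.593 (range −0.134 to 0.160). Cluster 22 held 73.3% of the Top2a and 57.8% of the Mki67 UMIs of transgenic beta-like cells, so its removal leaves others. Dividing cells outside it are therefore not argued against. Free RNA from dividing immune cells stays open, since in alpha-like cells the median over all 30 members was 0.136 (range −0.157 to 0.182) but 15 had under 50 UMIs, and some of those that lead in beta-like cells also stood higher there, Top2a with 1 and 14 UMIs and Cdc20 with 2 and 18. Within cluster 9 alone the list median was −0.14, but its libraries differed in other ways too, with the sex-linked list at 0.66 and Uty at 1.37. More dividing beta-like cells in the transgenic library may account for part of the difference, which remains a hypothesis. Effects of the transgene, of animal, or of sex beyond the cells with Y-linked UMIs and no Xist were not tested.

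Genes with a miR-503 seed site were lower in transgenic beta-like cells. Against UTR length or expression as the whole cause stands a percentile of 0.02 among lists matched on both, and against female cells a percentile of 0 with cells limited to Y-linked UMIs and no Xist (700 genes, shift −0.0816). A difference shared by all cells stays open: taken against the median of matched lists, genes with a site stood at −0.0342 in beta-like cells (bootstrap −0.0547 to −0.0187) and at −0.0233 in alpha-like cells (−0.0491 to −0.00545), inside the beta-like interval. So does a general shift between beta-cell states, as in cluster 9 the percentile was 4.2 (353 genes, bootstrap of the shift −0.0623 to 0.0188), where the same 353 genes over all beta-like cells lay at 0.03. Repression by the transgene is 1 candidate explanation among these, and animals and sex beyond these cells were not tested.

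Insulin transcripts took a larger share of UMIs in transgenic beta-like cells. Against deeper cells as the cause, the smallest difference over 10 bins of depth was 4.70 percentage points, and against female cells, cells with Y-linked UMIs and no Xist differed by 9.99 points. The test took free insulin RNA to add as many points to every class. The larger difference in macrophage-like and alpha-like cells was 1.21 points, in macrophage-like cells, against 9.75 in beta-like cells. The bound set for excluding any part was lower than 1.21 and was missed, so free RNA may add a part. Equal points need not hold, because wild type insulin shares were 50.6% in beta-like and 2.87% in macrophage-like cells. The size of that part is therefore not settled. Transgene, animals and the mix of beta-cell states between the libraries stay open and were not tested.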

How the results depend on the processing

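The settings with clusters split again, cells with Y-linked UMIs and no Xist, cluster 9 alone and without cluster 22 were chosen after the data were seen. No paired analysis was possible because each group has 1 library and the labels link no animals. A minimum of 3000 UMIs removed no cell. With no CPM minimum, 191 genes were at least 2-fold higher and 107 lower. Total scaling gave 125 and 298 by its construction, since insulin lowers other genes, and turned the oxidative phosphorylation list to −0.149 and the alpha function list to −0.0391. Fewer or more genes entered with at least 300 UMIs (79 and 52), at least 30 UMIs (437 and 234) or no minimum (2173 and 1716), and 1.5-fold gave 496 and 419. Cluster 9 alone, with fewer cells, gave 20 and 15, cell cycle −0.142, oxidative phosphorylation −0.0390 and a seed site shift of −0.0237, and the cause was not tested. The seed shift ran from −0.0928 to −0.0663 over the other 16 alternatives. They include other site sequences, of which the 8-base site gave the low end. Scaling by total UMIs, with or without hormone and mitochondrial genes, and the minimum of 3000 UMIs could not change this shift.

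The beta-like share was lower in the transgenic library in 10 of 10 alternatives, and the alpha-like and delta-like shares were higher in 10 of 10, while the gamma-like share was higher in 8 and lower in 2. Beta-like shares of wild type and transgenic cells were 71.5% and 51.1% with up to 20% mitochondrial UMIs, 65.8% and 60.5% with each library clustered alone, and 70.9% and 62.4% with clusters split again. With at most 5% mitochondrial UMIs the wild type library had 71.4% beta-like and 11.2% alpha-like cells, and with no doublets removed the transgenic library had 63.2% beta-like cells. Alpha-like shares were 7.58% and 12.8% at resolution 2.0 and 8.09% and 14.6% with clusters split again. For these shares the cause was not tested.

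Of 23 list medians, 17 kept their sign under total scaling, 21 with per-cell means, 22 with at most 5% mitochondrial UMIs and 22 without cluster 22, as did 17 of 22 in cluster 9 alone and 23 in each other setting. Of 121 named genes 113 kept their sign under total scaling, 97 of 101 in cluster 9 alone and 118 of 119 in cells with Y-linked UMIs and no Xist. In the other settings all 120 or 121 did.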

Other observations

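Macrophage-like and B cell-like cells were described only after the data had been seen, and each falls below the minimum of 50 cells in 1 library. In macrophage-like cells (65 wild type, 42 transgenic) the interferon, senescence and macrophage activation lists were lower in the transgenic library. The interferon list had 19 of 22 members lower with a median of −0.98, below the range of matched random lists (−0.23 to 0.12). Interferon beta itself, Ifnb1, stood at −2.16 (−3.12 to −1.31), the cytokine Il6 at −2.88 (−3.92 to −1.99), Ifit2 at −2.25 (−2.87 to −1.69) and Rsad2 at −1.94 (−2.11 to −1.78). The senescence and secretome list had 14 of 18 lower with a median of −0.44, and the macrophage activation list 11 of 15 lower at −0.34. Higher were complement C3 at 3.58 (2.80 to 4.46), the lipid carrier Fabp5 at 2.66 (2.14 to 3.22), the lysosomal protease Ctsd at 2.18 (1.99 to 2.37) and the lysozyme Lyz2 at 1.96 (1.89 to 2.03). The chemokines Cxcl1 and Ccl2 were at 1.57 and 1.56. The immediate early list was at −0.20 (17 of 24 lower), oxidative stress at −0.17 and MHC class I at 0.06 (8 of 13 higher).

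In B cell-like cells (21 wild type, 54 transgenic) the genes given here were picked after their values were seen. Jchain, which joins secreted antibodies, was at 3.44 (2.49 to 4.58), the chemokine Ccl4 at 2.62, the homing receptor Ccr7 at 1.96 and the calcium-binding S100a6 at −3.28 (−3.84 to −2.76). The interferon list had 8 of 14 members higher with a median of 0.14 at percentile 52.7, unlike in macrophage-like cells. An unnamed cluster led by Fscn1, Ccl22 and Ccl17 held 3 wild type and 36 transgenic cells, and an unnamed cluster with acinar genes held 14 and 22.

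Hormone transcripts of other endocrine cells were found in beta-like and macrophage-like cells. Among cells thinned to 3000 UMIs Gcg was detected in 99.3% of wild type and 99.96% of transgenic beta-like cells, and in 100% of macrophage-like cells of each library. Sst was detected in 39.4% and 60.4% of beta-like cells, and in 46.2% and 76.2% of macrophage-like cells. In transgenic beta-like cells insulin made up 58.2% of UMIs in 179 cells with Xist and no Y-linked UMI, and 60.3% in 1815 cells with Y-linked UMIs and no Xist.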
